A study of Mus musculus with 74 samples.

How the data were processed

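Gene expression was measured on 74 dual-channel mouse cDNA arrays of 8976 probes. Per the labels, channel 1 held RNA from cells without TGF-β and channel 2 RNA from cells given TGF-β. An exception is S3KO at 0.3 h, where a label names no TGF-β for both channels, against the title. By the labels, each array of the 0 h groups held RNA without TGF-β in both channels. Those 0 h arrays are self-hybridisations and give the background ratio of each probe. The arrays fall into 25 groups: 5 lines (S2WT, S3WT, S2KO, S3KO and U0126) by 5 times (0, 0.3, 1, 2 and 4 h), with 3 arrays per group except S3KO at 1 h, which has 2.

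The deposited values are log2 ratios of the channels of an array. They are signed, and 1344 of them equal 16.61, the log2 of a ratio of 100000, which was read as a ratio with an empty denominator and set to missing. No value equals 0, and 41670 of the cells are blank. The dyes, scanner, background correction and normalisation are not given in the sources used here, and channel intensities and signal-over-background values were not used here, so the signal behind each ratio is unknown. The number of arrays limits the precision. The direction of the ratio is not stated either. It was taken as channel 2 over channel 1, which is likely but not certain: a list of TGF-β-induced genes fixed in advance was higher on the treated arrays of both wild-type lines by limma's cameraPR before adjustment. Each array was centred on its median, because the medians as deposited ranged from -0.60 to 0.22, so every change is relative to the median probe of its array.

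Differences were estimated in R 4.3.3 by least squares for each probe, from group means over all 74 arrays, which share an estimate of the spread. The variances were moderated with the function squeezeVar of limma 3.58.1, and calls by limma below mean the resulting moderated t test. The response of a line was the mean of its 1, 2 and 4 h groups minus its own 0 h group. The response at 0.3 h used that group minus the 0 h group. Differences between lines were tested as differences of responses. A probe was tested when it was measured on at least 2 arrays of each group in the contrast, and p-values were adjusted by Benjamini-Hochberg within a contrast, with 0.05 as the threshold. "Called" below means past that threshold. These choices, the rule for named genes, the gene lists and a set of alternatives were fixed before the data were examined.

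The genes named in the text were drawn from a set given by a fixed rule. Only part of the set is described, and the rule does not say which part. Left out are, for example, Dancr in S2WT (1.51) and Wars2 in S3KO (-5.91), both against own 0 h arrays. The genes described therefore do not stand for all called ones. For each response and difference at 1 to 4 h, the 10 largest rises and 10 largest falls were taken among called probes with exactly 1 gene symbol that is not a clone identifier. For responses, each array at 1, 2 and 4 h also had to lie on the same side of the 0 h mean. If fewer than 3 passed, the 5 probes with the smallest p were taken. At 0.3 h the 5 largest each way were taken in the same manner. Up to 4 members with the smallest p were taken from each gene list, and Smad2, Smad3, Smad7, Ccn2, Junb, Skil, Id1, Id2 and Id3 were always included where a probe measured them. A gene on several probes was given by the probe with the smallest p. Gene symbols came from the platform's annotation, which gives 7348 probes a single symbol, 399 several and 1229 none, and 7274 of the single-symbol probes have a gene ID in the mouse RefSeq gene table. The files give no genome positions, so none are stated.

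Carry-over of a response to other lines was scored on each array as the mean of the signed log2 ratios over the probes called in a wild-type line. Arrays of pairs of the other lines were compared with a two-sided exact permutation test within each time, and the 12 pairs were adjusted together. Where probes were called against the pooled 0 h arrays, the 0 h arrays of the compared lines also helped to choose them. The 17 gene lists were tested with cameraPR on the moderated t values with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the lists within a contrast.

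The alternatives fixed beforehand were to test treated arrays against 0 without the 0 h arrays, to leave arrays uncentred, to scale arrays to a common spread, to keep only probes measured on every array, to add the replicate number of each line as a block, to fit only the lines compared, to weight arrays by quality, to average probes of a gene, and to leave out each array. The replicate block could be fitted for the responses against own 0 h arrays and their differences. Contrasts that set arrays of one line against another, as the pooled background and the direct comparison do, cannot be estimated with it. For a difference between lines, leaving out the 0 h arrays compares the treated arrays directly. Such a direct comparison keeps any difference in background between the lines. Added after the data were seen were a background pooled from the 0 h arrays of all 5 lines, or of the 4 lines other than S3KO, keeping the ceiling values, leaving out the S2WT 4 h arrays, and subtracting the 0 h scores of the lines in the carry-over test, with the 0 h arrays permuted too. The pooled background assumes that a probe's background ratio is shared by the lines. The genes named for it are part of the set that the same rule gives and were therefore chosen after the data were seen.

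The scripts were tested on simulated data made from permuted residuals, with 67 or 66 probes shifted at each size. For the S2WT response against its own 0 h arrays, 13.4% of probes shifted by 0.5 log2, 47.8% of those shifted by 1 and 89.4% of those shifted by 2 were called among 8331 tested, with 24 false calls of 124. With normally distributed noise there was 1 false call of 91. Against the pooled 0 h arrays, 34.3%, 70.1% and 93.9% of the same shift sizes were called among 7555 tested in S2WT, with 6 false calls of 138. The simulated groups had equal means before the shifts, so the lines shared a background by construction. Residuals were permuted for each probe separately, which removes any shared deviation of an array. The pooled figures therefore do not test whether the lines share a background. For S3KO minus S3WT against own 0 h arrays, 1.49% of probes shifted by 0.5 log2, 28.4% of those shifted by 1 and 72.7% of those shifted by 2 were called among 7153 tested. A simulated list of 20 probes shifted by 0.5 in S2WT was called by cameraPR, and 0 of 20 unshifted lists fell under 0.05.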

Results

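The data are log2 ratios from 74 dual-channel mouse arrays of 8976 probes that compare cells given TGF-β with cells that were not, within the same line. The lines are labelled S2WT, S3WT, S2KO, S3KO and U0126. S2 and S3 are not spelled out in the labels. In the published study that matches this design they stand for Smad2 and Smad3, the receptor-activated transcription factors of the TGF-β pathway. The arrays called U0126 here, after an inhibitor of the kinase MEK, have titles that set S2WT against U0126. Their channel labels name S2WT and U0126 together in both channels, without and with TGF-β, and were followed. If the titles named the channels instead, these ratios would hold an effect of the drug. Each line was sampled at 0, 0.3, 1, 2 and 4 h with 3 arrays per time, except 2 arrays for S3KO at 1 h. An array gave values for 7688 to 8713 probes, with a median of 5.84% of cells blank. The signal behind the ratios is unknown, and the number of arrays limits the precision. The S2WT 4 h arrays carry a 2 h label in another field, and the S3KO 0.3 h arrays carry a label without TGF-β for both channels. A ratio compares cells of a single line, so it does not check the knockouts. No probe carried the symbol Smad2 alone, and Ccn2, Junb, Id1, Id2 and Id3 were not measured by single-symbol probes either. The p-values measure the spread between arrays, which may be technical, because the labels do not say whether replicate arrays hold RNA from separate cultures.

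At 0 h both channels held RNA without TGF-β, yet limma called 26 probes away from 0 in S2WT, 262 in S3WT, 406 in S2KO, 273 in S3KO and 467 in U0126. Part of each ratio is therefore background that every response has to be set against. Across the 2244 probes measured on every array, the 0 h means of pairs of lines correlated with r from 0.10 to 0.70, and those of S3KO with the others with r from 0.10 to 0.14. These are correlations across genes, and genes are not independent replicates. Responses are therefore given against the line's own 0 h arrays, as designed, and also against the 0 h arrays of all 5 lines pooled. The pooled comparison was added after the data were seen and assumes that the lines share a background. A list of 6 measured TGF-β-induced genes was higher than other genes on the treated S2WT arrays, with a median log2 of 0.42 and 5 of 6 probes positive (cameraPR, unadjusted p = 0.0338). In S3WT its median was 0.10 with 3 of 6 positive (cameraPR, unadjusted p = 0.0292). Adjusted over the lists it passed in neither. The unadjusted p in S2WT was 0.0586 without centring (median 0.22) and 0.0716 with scaling (median 0.36), and in S3WT it was 0.0371 without centring, or 0.0855 with an estimated correlation. The ratio is read from this as likely channel 2 over channel 1. Values below are log2 changes ± SE from 9 treated arrays at 1 to 4 h, or 8 in S3KO, against 3 own or 15 pooled 0 h arrays. The calls use the spread over all 74 arrays. Fitted on the arrays of a single line, limma called 2 probes in S2WT, 2 in S3WT and 0 in S2KO, S3KO and U0126 against own 0 h arrays, with 426, 589 and 587 at an unadjusted p under 0.05 in the last 3.

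The first comparison asks what TGF-β changes in the wild-type line S2WT. Hbegf, the heparin-binding EGF-like growth factor, rose by 1.76 ± 0.37 against its own 0 h arrays (adjusted p = 0.0185, above the 0 h mean on 9 of 9 arrays) and by 1.81 ± 0.24 against the pooled ones (adjusted p = 8.4e-07). Gadd45b, a growth-arrest protein of stress signalling, rose by 1.45 ± 0.33 and 1.35 ± 0.21 against the same backgrounds. The cold-shock-domain RNA-binding protein gene Csdc2 rose by 1.38 ± 0.29 and 1.19 ± 0.18 on probe 2622, and its 1 other probe is not described here. Arid5b, a DNA-binding cofactor of histone demethylation, fell by 0.95 ± 0.17 (adjusted p = 0.00394) and 0.90 ± 0.11 (adjusted p = 3.5e-07). Hbegf climbed over time, with means of 0.15, 0.26, 1.33, 1.84 and 2.56 at 0, 0.3, 1, 2 and 4 h, whereas Gadd45b was already at 1.96 at 1 h and stood at 1.78 at 4 h. The S2WT 4 h arrays carry a 2 h label in another field, so the step from 2 to 4 h is uncertain.

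Against its own 0 h arrays 16 probes were called in S2WT, 11 higher and 5 lower among 8331 tested. Foxo1, a forkhead transcription factor, rose by 1.6 ± 0.29 on probe 2461, and its 2 other probes are not described here. Derl1 of endoplasmic reticulum protein degradation rose by 0.78 ± 0.15. Aass, an enzyme of lysine breakdown, fell by 1.87 ± 0.39, but was at -0.40 with the treated arrays tested against 0 (adjusted p = 0.115). Lrig3, a membrane protein with leucine-rich repeats, rose by 1.63 ± 0.35, but its mean at 1 h of 2.91 ± 2.88 (SD, n = 2) came from 2 arrays far apart. Against the pooled 0 h arrays 96 probes were called, 64 higher and 32 lower among 7555 tested, and 10 of the 16 were among them. They include Snai1, a zinc-finger repressor of epithelial genes (0.92 ± 0.19), the repressor Bhlhe40 (0.77 ± 0.18), the immediate early gene Ier2 (1.05 ± 0.25) and the ubiquitin ligase gene Smurf2 (0.37 ± 0.07). Both called Tgfbr3 probes, for the TGF-β co-receptor betaglycan, were lower, by -1.24 ± 0.29 and -0.79 ± 0.16, while its other probe was at -0.29 and did not pass. With the S3KO 0 h arrays left out of the pool 61 probes were called, and the first of these Tgfbr3 probes was at -0.61 (adjusted p = 0.508). In the pooled comparison Hbegf, Gadd45b, Csdc2, Snai1, Bhlhe40 and Smurf2 stayed called in 24 of 24 fits that each left out 1 array. Without centring the median of all tested probes in S2WT was -0.17. The splits then became 2 higher and 11 lower against own and 24 higher and 271 lower against pooled 0 h arrays, so the direction of the count rests on centring. With scaling the splits were 33 and 25, and 21 and 6. Leaving out 1 array gave 75 own calls without 0 h replicate 2, 28 without 0 h replicate 3 and 26 without 4 h replicate 2. It gave 55 pooled calls without 1 h replicate 1. Hbegf lost its own-background call without 0 h replicate 1 or 3, with adjusted p up to 0.0878, and Gadd45b and Csdc2 kept theirs in 7 and 10 of 12 fits, Lrig3 in 8 of 10 and Derl1 in 11 of 12. Derl1 moved between 0.58 and 0.90.

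The same question was asked of S3WT, the other wild-type line. Bhlhe40 rose by 1.27 ± 0.28 against own 0 h arrays (adjusted p = 0.047) and by 1.08 ± 0.18 against pooled ones (adjusted p = 0.0011). Hbegf rose by 1.36 ± 0.24 against the pooled arrays (adjusted p = 0.00176), with means of 0.15, 0.36, 1.14, 1.63 and 1.61 over the time course. Against the pooled arrays Klf10, a TGF-β-inducible zinc-finger factor, rose by 0.75 ± 0.16, Gadd45b by 0.95 ± 0.21, and Noct, the circadian gene nocturnin, by 0.90, while the metallothionein gene Mt1 fell by 0.67. With the S3KO 0 h arrays left out of the pool, only Hbegf (1.31) and Bhlhe40 (1.15) of these stayed called. Klf10, Noct and Mt1 were then each at an adjusted p of 0.0653 and Gadd45b at 0.133.

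Own 0 h arrays gave 10 calls in S3WT, 8 higher and 2 lower among 8340 tested. The pooled ones gave 11, 9 higher and 2 lower among 7558 tested, with 1 of the 10 in common. The 8 higher include Tat, a tyrosine-degrading aminotransferase (3.62 ± 0.73), Ankrd27 (3.16 ± 0.52) and the kinase gene Dapk2 (2.17 ± 0.39). The lower ones include the interferon-induced membrane protein gene Ifitm3 (-1.24 ± 0.26). The treated arrays alone do not show these changes, as their means without subtraction were 0.51 for Tat, -0.38 for Ankrd27, 0.38 for Dapk2 and -0.14 for Ifitm3, and none passed against 0. The sign of Ankrd27 thus turned. Leaving out 1 array moved Ankrd27 between 1.67 and 4.11, Dapk2 between 1.49 and 3.18, each losing its call without 0 h replicate 3. Ifitm3 moved between -1.57 and -0.61 and lost its call without 0 h replicate 2 or 4 h replicate 2, and Tat lost it without 4 h replicate 2. Without centring the splits were 2 higher and 1 lower against own and 5 and 0 against pooled 0 h arrays, and with scaling 17 and 8, and 26 and 8. Among fits that left out 1 array, Hbegf and Bhlhe40 kept the pooled call in 24 of 24, Klf10 in 18, Gadd45b in 17 and Noct and Mt1 in 10 each. Bhlhe40 kept its own-background call in 7 of 12. The own count of 10 moved to between 2 without 4 h replicate 2 and 57 without 0 h replicate 3. The pooled count of 11 moved to between 3 without S2WT 0 h replicate 1 and 24 without S3WT 4 h replicate 3.

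S2KO tests what TGF-β changes where, by its name, Smad2 was removed. Hbegf rose by 2.27 ± 0.37 against own 0 h arrays (adjusted p = 0.0011) and by 2.23 ± 0.24 against the pooled ones (adjusted p = 1.31e-09), and reached 3.20 at 4 h. Gadd45b rose by 1.72 ± 0.33 and 2.07 ± 0.21, Snai1 by 1.63 ± 0.29 and 1.83 ± 0.19, and Skil, the Smad corepressor SnoN, by 1.21 ± 0.24 and 1.22 ± 0.15. These 4 genes were called in each of 12 own and 24 pooled fits that left out 1 array. Txnip, the thioredoxin inhibitor, fell by 1.09 ± 0.24 on probe 249 (called in 11 of 12 own fits), while its probe 7112 was at -0.06 against the pooled arrays and did not pass.

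The S2KO response held 42 calls against own 0 h arrays, 32 higher and 10 lower among 8151 tested. Against pooled ones there were 185, 142 higher and 43 lower among 7444 tested, with 23 of the 42 in common. Genes of the pathway itself were among the pooled calls: the type I receptor gene Tgfbr1 (1.06 ± 0.17), the ubiquitin ligase gene Smurf1 (0.62 ± 0.11), and the co-receptor genes Eng (-1.08 ± 0.24) and Tgfbr3 (-1.10 ± 0.28). Without the S3KO 0 h arrays in the pool 144 probes were called, and Tgfbr3 (-0.48, adjusted p = 0.563) was not. Matricellular Ccn1 rose by 1.39 ± 0.28 and the small GTPase gene Rhob by 1.14 ± 0.21 in the same comparison. Of the actin and contractile list 3 genes rose, the LIM protein gene Csrp2 (0.88 ± 0.17) and the integrin genes Itgb1 (0.58 ± 0.14) and Itga5 (0.59 ± 0.17), a list whose call was lost with an estimated correlation (adjusted p = 0.084). Itga5 kept its call in 11 of 24 fits that left out 1 array, and lost it without the S3KO 0 h arrays in the pool (adjusted p = 0.066). A further Itgb1 probe was at -0.38 against own 0 h arrays (adjusted p = 0.706), where the called one was at 0.24 (adjusted p = 0.914). Cdc6, which licenses replication origins, fell by 2.09 ± 0.47 on the probe that could be tested. Own-background calls of growth factor binding protein Igfbp5 (3.30 ± 0.74) and cyclin D1, Ccnd1 (-2.0 ± 0.51), were kept in 6 of 8 and 4 of 12 fits that left out 1 array. Igfbp5 moved between 2.02 and 5.15 in these and Ccnd1 between -2.99 and -0.22, so neither size is firm. Tested against 0, the treated arrays had Igfbp5 at -0.45, a turned sign, and Ccnd1 at -0.04. Of the 185 probes, 13 were farthest from 0 h at 1 h, 81 at 2 h and 90 at 4 h. Without centring the splits were 11 and 1 against own and 62 and 66 against pooled 0 h arrays, and with scaling 7 probes were called against own arrays and the pooled split was 52 and 12. The own count moved to 16 without 1 h replicate 1 or without 4 h replicate 3, 18 without 4 h replicate 1, 25 without 2 h replicate 1, 65 without 0 h replicate 1, 71 without 4 h replicate 2 and 92 without 0 h replicate 3. The pooled count moved to 117 without 4 h replicate 1 and 325 without 4 h replicate 2.

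Whether S2KO responds differently from S2WT was tested as a difference of responses. As designed, 3 probes were called, all higher in S2KO among 7767 tested: Gys2, liver glycogen synthase (4.33 ± 0.88), Aass (2.40 ± 0.50) and the zinc transporter gene Slc39a10 (1.13 ± 0.24). On the treated arrays alone the differences were 0.81, -0.03 and 0.64, so the sign of Aass turned. No gene named above for S2KO passed this test, for example Hbegf with a difference of 0.51 (adjusted p = 0.895). When the treated arrays of both lines were compared directly, 26 probes were called, 14 higher and 12 lower in S2KO among 7987 tested. This comparison keeps any difference in background between the lines, whose 0 h means correlated with r = 0.54. It therefore does not by itself show a different response to TGF-β. Higher in S2KO were Snai1 (0.91 ± 0.21), Skil (0.70 ± 0.17), the helix-loop-helix inhibitor gene Id4 (1.67 ± 0.38), Slc39a10 (0.64 ± 0.12) and the coactivator TAZ, Wwtr1 (0.50 ± 0.12). Lower were Lrig3 (-1.39 ± 0.25), Eng (-1.30 ± 0.27) and the mitotic kinase gene Pbk (-1.28 ± 0.21). Hbegf differed by 0.43 (adjusted p = 0.59), Gadd45b by 0.72 (adjusted p = 0.2) and Tgfbr1 by 0.74 (adjusted p = 0.0831), which did not pass. Of 18 arrays left out in turn, Slc39a10 kept this call in 18 of 18 fits, Lrig3 and Eng in 16 of 16 and Pbk in 14 of 14, and the remaining fits could not test these last 3. For Lrig3 the untested fits leave out either of its 2 S2WT arrays at 1 h, which lay far apart. Its 16 of 16 therefore does not show that the call holds without either of them. Snai1 kept its direct call in 13 of 18 fits, Id4 in 15, Wwtr1 in 10 and Skil in 6. The direct split was 15 and 7 without centring, 3 and 3 with scaling and 46 and 24 with array weights. The direct count moved to 10 without S2WT 2 h replicate 1, 12 without S2KO 4 h replicate 3, 16 without S2KO 2 h replicate 1, 43 without S2WT 1 h replicate 2 or 2 h replicate 3, 52 without S2KO 2 h replicate 2 and 71 without S2KO 4 h replicate 2. The designed count of 3 fell to 0 by limma in 16 of 24 fits that left out 1 array, with 360 to 576 probes at an unadjusted p under 0.05, and rose to 12 without S2WT 0 h replicate 2. Gys2, which moved between 3.28 and 5.30, kept its call in 4 of 20 such fits, Aass in 4 of 18 and Slc39a10 in 5 of 24.

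S3KO tests what TGF-β changes where, by its name, Smad3 was removed. None of the genes that rose most firmly in the other lines was called here: Hbegf was at 0.12, Gadd45b at -0.03, Snai1 at -0.27, Bhlhe40 at 0.14 and Skil at 0.22 against the pooled 0 h arrays. The mean of Hbegf was -0.08, 0.31, -0.43, 0.68 and 0.42 over the time course. The 1 h group counts as much as the 2 h and 4 h groups in these responses but holds 2 arrays. Of these, replicate 2 correlated with the 0 h mean of the other lines at r = -0.38 and replicate 3 at r = 0.55. What sets replicate 2 apart is not given in the sources used here. The values above therefore do not show that the line lacks the response. A single probe passed against the pooled arrays, Asap3, a GTPase-activating protein of the cytoskeleton (-0.65 ± 0.12, adjusted p = 0.00846), and not without the S3KO 0 h arrays in the pool (-0.53, adjusted p = 0.131).

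Against its own 0 h arrays S3KO had 114 calls, 51 higher and 63 lower among 7469 tested, of which only Asap3 was also called against the pooled ones. Tnc, the matrix protein tenascin C, was called at 2.33 ± 0.40, the ubiquitin ligase scaffold gene Cul3 at 2.33 ± 0.42, Tgfbr3 at -3.45 ± 0.51 on 1 of 3 probes, and the corepressor gene Rere at -4.75 ± 0.81. Tested against 0, the treated arrays had Tnc at 0.06, Cul3 at -0.13, a turned sign, Rere at -0.33 and Tgfbr3 at -0.80, and none passed. Against the pooled arrays Tnc was at 0.55 (adjusted p = 0.831) and the same Tgfbr3 probe at -0.93 (adjusted p = 0.59). The 0 h arrays of S3KO had the 2nd highest within-group spread of the 25 groups (SD 0.40) and a mean of 11.3% of cells blank. Over 2244 probes, replicates 1 and 2 of these correlated with the 0 h mean of the other lines at r = -0.16 and r = -0.10, and replicate 3 at r = 0.58. Leaving out 1 array moved the 114 calls to 45 without 0 h replicate 2, 68 without 2 h replicate 1 and 418 without 0 h replicate 3. The 1 pooled call became 0 without 0 h replicate 3, 17 without 1 h replicate 2 and 25 without 1 h replicate 3. Without centring the median of all tested probes was -0.11 and the split 19 higher and 67 lower.

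The difference between S3KO and S3WT gave 9 calls as designed, all lower in S3KO among 7153 tested. They were Scgb1a1, a secretory-cell protein gene (-5.03 ± 1.05), Tgfbr3 (-3.44 ± 0.67), Ankrd27 (-3.41 ± 0.75), Tmed5 (-2.87 ± 0.66), Rnf144a (-2.05 ± 0.44), Tut4 (-1.96 ± 0.37), the centromere histone gene Cenpa (-1.79 ± 0.40), the nuclear receptor gene Rora (-1.65 ± 0.37) and Asap3 (-1.20 ± 0.27). On the treated arrays alone Rnf144a (0.57) and Ankrd27 (0.18) turned to higher in S3KO, and the other 7 lay between -1.14 and -0.17. Of 23 arrays left out in turn, Tgfbr3 kept its call in 21 of 21 fits that could test it, and Tut4 in 22 of 23. The others kept it less often: Ankrd27 in 15 of 23, Scgb1a1 and Rnf144a in 12 of 17, Rora in 10 of 21, Asap3 in 8 of 21, Cenpa in 8 of 23 and Tmed5 in 5 of 23. Ankrd27 moved between -4.36 and -1.93 and Tmed5 between -4.0 and -1.99. Directly compared, the treated arrays gave 0 calls by limma among 7534 tested, with 448 probes at an unadjusted p under 0.05. Hbegf was at -1.24 ± 0.27 (adjusted p = 0.0696), Bhlhe40 at -0.95 ± 0.21 (adjusted p = 0.0696) and Gadd45b at -0.98 (adjusted p = 0.173). As designed, the Hbegf difference was -1.0 (adjusted p = 0.589). The 9 calls became 0 without S3KO 0 h replicate 2, 48 without S3KO 0 h replicate 1 and 189 without S3KO 0 h replicate 3. The direct count rose to 39 without S3KO 1 h replicate 3. With scaling the splits were 13 and 21, and 4 and 19 for the direct comparison, which gave 6 lower probes with array weights.

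The U0126 arrays ask what TGF-β changes when MEK is inhibited. Txnip fell by 1.18 ± 0.24 on probe 249 against own 0 h arrays (adjusted p = 0.0156) and was at -1.20 ± 0.15 against the pooled ones (adjusted p = 1.17e-06). Its mean was -1.58 at 2 h, while its probe 7112 was at -0.10 against the pooled arrays (adjusted p = 0.934). Against the pooled arrays Hbegf rose by 1.15 ± 0.24, Csdc2 by 0.91 ± 0.18, Snai1 by 0.78 ± 0.19, Gadd45b by 0.82 ± 0.21, the lipase gene Mgll by 0.86 ± 0.19 and the mitochondrial carnitine carrier gene Slc25a20 by 1.31 ± 0.24. Gsk3b, a kinase of Wnt and glycogen signalling, fell by 1.0 ± 0.16 on probe 6410, whereas probe 1358, 1 of its 3 other probes, was at -0.31 (adjusted p = 0.484).

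Own 0 h arrays gave 6 calls, 4 higher and 2 lower among 8349 tested, led by Rprd1b, which binds RNA polymerase II (2.82 ± 0.37), and the Myc antagonist gene Mxi1 (2.43 ± 0.46). Both signs turned on the treated arrays tested against 0 (Rprd1b -0.46, adjusted p = 0.0405, and Mxi1 -0.17, adjusted p = 0.691), so these calls rest on the U0126 0 h arrays. Pooled ones gave 59, 33 higher and 26 lower among 7543 tested, with 2 of the 6 in common. In fits that left out 1 array, Txnip, Csdc2 and Mgll kept the pooled call in 24 of 24, Snai1 in 20 and Gadd45b in 10. With the S3KO 0 h arrays left out of the pool 25 probes were called, and Snai1 (adjusted p = 0.0848) and Gadd45b (adjusted p = 0.158) were not. Without U0126 0 h replicate 2 the own-background calls of Txnip and Mxi1 were lost, and Mxi1 fell to 1.42. The 6 calls became 29 without it, 24 without 0 h replicate 1 and 26 without 0 h replicate 3. The 59 calls became 23 without 4 h replicate 1, 36 without 2 h replicate 2, 38 without 0 h replicate 1 or 2 h replicate 3, and 104 without 1 h replicate 1. The own split was 3 and 0 without centring and 6 and 1 with scaling. The pooled split was 11 and 9 without centring, 51 and 31 with scaling and 102 and 69 with array weights.

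U0126 and S2WT responses differed at 2 probes as designed, both higher with U0126 among 7938 tested: Rprd1b (2.89 ± 0.49) and the repair and transcription factor gene Gtf2h3 (3.60 ± 0.70). On the treated arrays alone Rprd1b turned to -0.11 and Gtf2h3 was at 0.54, after 0 h differences of -3.0 and -3.06. Of 24 arrays left out in turn, Rprd1b kept this call in 22 of 22 fits that could test it. Gtf2h3 kept it in 22 of 24 and moved between 2.0 and 4.62. The count became 0 without U0126 0 h replicate 3 and 7 without S2WT 0 h replicate 2 or U0126 0 h replicate 2. Direct comparison of the treated arrays gave 0 calls by limma among 8162 tested, with 398 at an unadjusted p under 0.05. Hbegf differed by -0.65 (adjusted p = 0.982), Lrig3 by -0.81 (adjusted p = 0.774) and Gsk3b by -0.65 ± 0.18 (adjusted p = 0.774). Without centring the median difference over all probes was 0.26. The direct comparison called 1 probe, lower with U0126, with array weights and also without U0126 4 h replicate 3. The 0 calls do not show that the responses are alike. On the 11 probes called in S3WT against the pooled 0 h arrays, S2WT scored above U0126 by 0.16 (adjusted p = 0.0228, exact permutation). With the 0 h scores subtracted the difference was 0.25 (adjusted p = 0.0626, exact permutation). The 0 h arrays of these lines also helped to choose the 11 probes.

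The S3WT and S2WT responses were compared to see how far the wild-type lines differ by themselves. By difference of responses limma called 0 of 7882 probes, with 419 at an unadjusted p under 0.05. Directly compared, 17 were called among 8126 tested, 9 higher and 8 lower in S3WT. Differences in background between the lines, whose 0 h means correlated with r = 0.52, stay in this comparison. Lrig3 was lower in S3WT (-1.39 ± 0.25), as were the TNF receptor gene Tnfrsf1b (-0.77 ± 0.15) and Entpd4 (-0.49 ± 0.10), and the last 2 kept the call in 18 of 18 fits that left out 1 array. Lrig3 kept it in 16 of 16, as it could not be tested without either of its 2 arrays of S2WT at 1 h, which lay far apart. Txnip (0.79 ± 0.17) and Arid5b (0.59 ± 0.12) were higher, with calls kept in 15 of 18 and 13 of 16 fits. Without centring, where the median difference over all probes was 0.12, the direct split was 342 and 4. With scaling it was 3 and 3, and with array weights 136 and 137, so this count is not firm. The direct count here moved to 5 without S2WT 2 h replicate 1 and 87 without S3WT 2 h replicate 1.

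**Figure D1:**
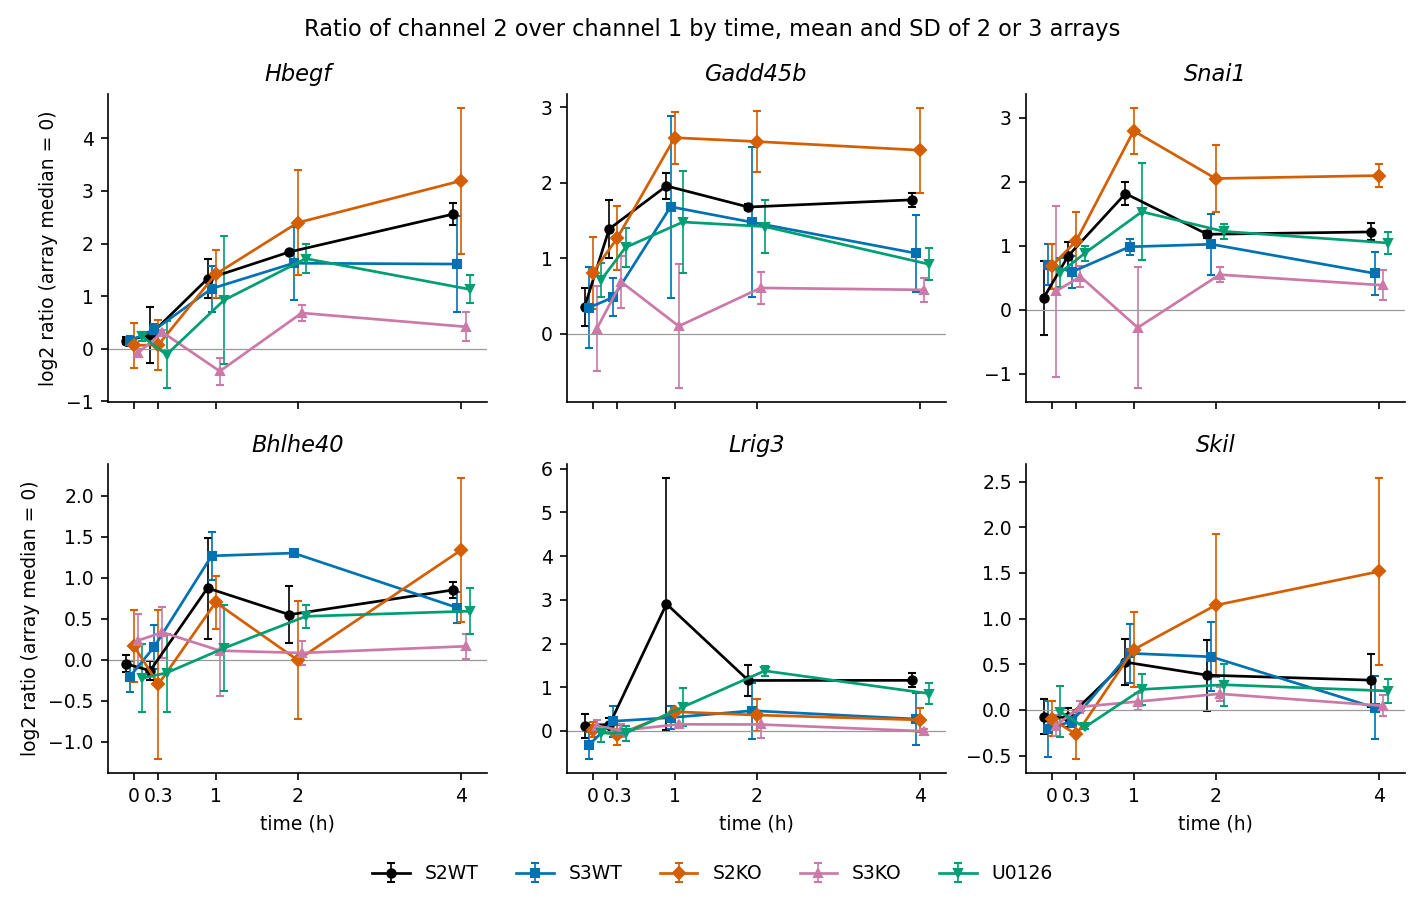
Mean log2 ratio (array median = 0) of Hbegf, Gadd45b, Snai1, Bhlhe40, Lrig3 and Skil against time in h for the 5 lines, with bars of 1 SD over 2 or 3 arrays. Hbegf reached 2.56 in S2WT and 3.20 in S2KO at 4 h and 0.42 in S3KO. Another label of the S2WT 4 h arrays gives 2 h.

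Whether the probes called in a wild-type line moved in the other lines was scored per array, as the mean signed log2 ratio over those probes. The 16 probes called in S2WT scored 0.83 ± 0.22 in S2KO (SD, n = 9), 0.62 ± 0.16 in U0126 (n = 9), 0.42 ± 0.26 in S3WT (n = 9) and 0.19 ± 0.16 in S3KO (n = 8). The 0 h scores of these lines were 0.38, 0.29, 0.04 and -0.04. S3KO scored below S2KO by 0.66 in the two-sided exact permutation test within time (p = 0.00025, the smallest it can give, adjusted p = 0.002). U0126 scored above S3KO (difference of S3KO minus U0126 -0.45, adjusted p = 0.002, exact permutation). S3WT scored above S3KO by 0.25 (adjusted p = 0.0454, exact permutation), a difference that turned to -0.0417 with scaling, and was 0.0405 without centring and 0.0274 with the probes called against 0. These tests compare treated scores and leave the 0 h scores in. With the 0 h scores subtracted, a test added after the data were seen in which the 0 h arrays are permuted too, S2KO exceeded S3KO by 0.24 (adjusted p = 0.818, exact permutation) and S3WT exceeded it by 0.17 (adjusted p = 0.818, exact permutation), so neither change was shown to differ. The 10 probes called in S3WT scored 0.18 in S2WT, 0.13 in U0126, -0.01 in S2KO and -0.09 in S3KO, with 0 h scores of 0.01, -0.25, -0.34 and 0.08. S2WT exceeded S3KO by 0.28 on these (adjusted p = 0.002, exact permutation), and by 0.35 with the 0 h scores subtracted (adjusted p = 0.818, exact permutation). The 1 pair of 12 that passed with subtraction was S3KO minus U0126 on these probes (-0.55, adjusted p = 0.0135, exact permutation). With the 96 and 11 probes called against the pooled 0 h arrays, S3KO was again lowest, at 0.13 and 0.16 against 0.60 and 0.93 in S2KO. The 0 h scores were -0.11 and -0.11 against 0.08 and 0.02. With these subtracted, S3KO stayed below on the 11 probes called in S3WT, by 0.66 against S2KO (adjusted p = 0.0382, exact permutation) and by 0.49 against S2WT (adjusted p = 0.0287, exact permutation). S3KO minus U0126 was -0.25 on these and did not pass (adjusted p = 0.228, exact permutation). On the 96 the difference from S2KO was 0.29 (adjusted p = 0.277, exact permutation). The 0 h arrays subtracted here also helped to choose the 96 and 11 probes, so these differences are not independent of that choice. Without the S3KO 0 h arrays in the pool, S3WT had 2 calls in place of 11. Of the 12 pairs of lines 8 passed by treated scores, 10 with the pooled 0 h arrays, 3 without centring, 1 with scaling and 1 with the own-background 0 h scores subtracted. Scaling left S2WT above S3KO by 0.21 on the probes called in S3WT (adjusted p = 0.009, exact permutation).

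**Figure D2:**
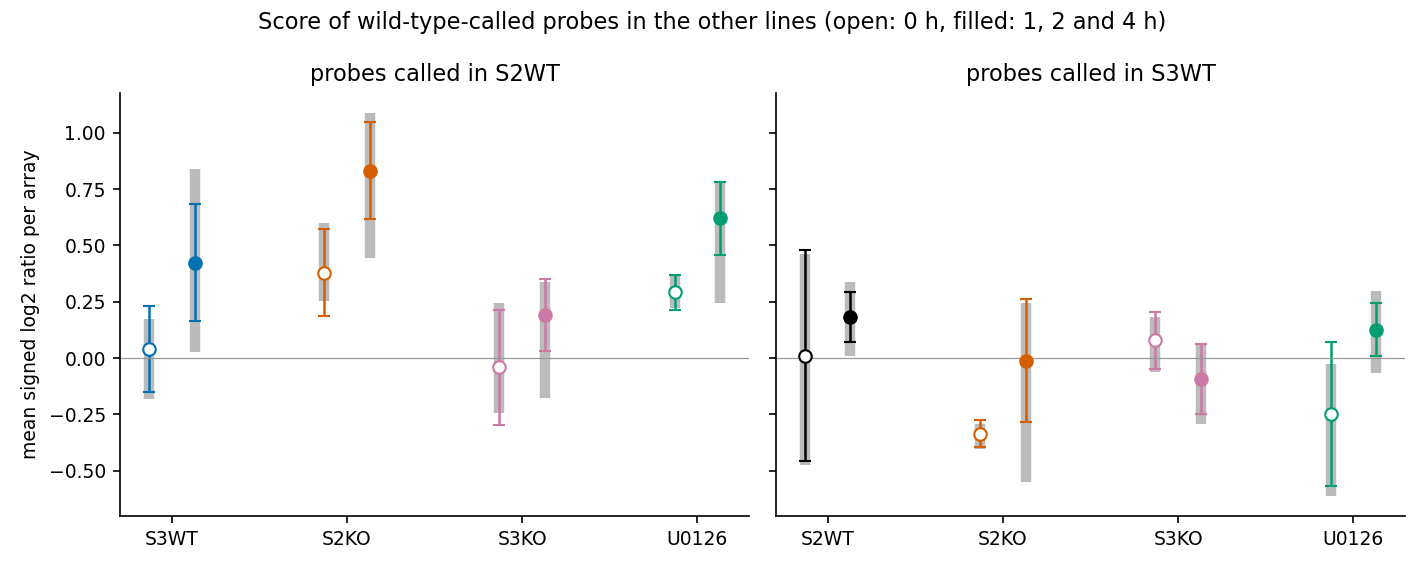
Mean signed log2 ratio per array over the probes called in S2WT and in S3WT, in the lines not used to choose them, at 0 h (open) and at 1, 2 and 4 h (filled), where points are means, bars 1 SD and grey lines run from the lowest to the highest array. On the 16 probes called in S2WT the treated mean was 0.83 in S2KO and 0.19 in S3KO.

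At 0.3 h few probes were called outside S3KO against own 0 h arrays, which did not hold against the pooled ones. In S2WT limma called 0 of 8450 probes, with 520 at an unadjusted p under 0.05, and Aass had the smallest p (-2.35, adjusted p = 0.0842). S3WT had 13 calls, 8 higher and 5 lower, with the ephrin receptor gene Epha8 at 5.32 and Tat at 4.69. S2KO had 2, 1 of them the interferon lambda receptor gene Ifnlr1 (-3.57). U0126 had 3, with Rprd1b at 3.60 ± 0.43 and the leukocyte tetraspanin gene Cd53 at -2.96 ± 0.59. S3KO had 70 calls, 29 higher and 41 lower, with the peptide hormone gene Apln at 5.63 and Tnc at 2.34 ± 0.46. A label of the S3KO 0.3 h arrays names no TGF-β for both channels, so these calls may not be a response to it. They also rest on the S3KO 0 h arrays, of which replicates 1 and 2 stood apart from the 0 h mean of the other lines (r = -0.16 and r = -0.10). Among fits that left out 1 array, Ifnlr1 kept its call in 5 of 6, Cd53 in 2 of 6 and Apln in 3 of 4. Tested against 0, the 0.3 h arrays had Rprd1b at 0.32, Tnc at 0.07, Tat at 1.6 and Apln at 2.18, none of which passed. The pooled 0 h arrays gave 5, 15, 31, 5 and 38 calls in S2WT, S3WT, S2KO, S3KO and U0126. Leaving out 1 array gave 1 to 21 calls in S2WT, 4 to 22 in S3WT, 1 to 63 in S2KO, 17 to 299 in S3KO and 0 to 28 in U0126. The highest came, in the same order, without 0.3 h replicate 1, 0 h replicate 3, 0.3 h replicate 2, 0 h replicate 3 and 0.3 h replicate 3. Without centring the U0126 split of 2 and 1 became 2 and 0, and with scaling it became 1 and 0 in U0126 and in S2KO.

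**Figure D3:**
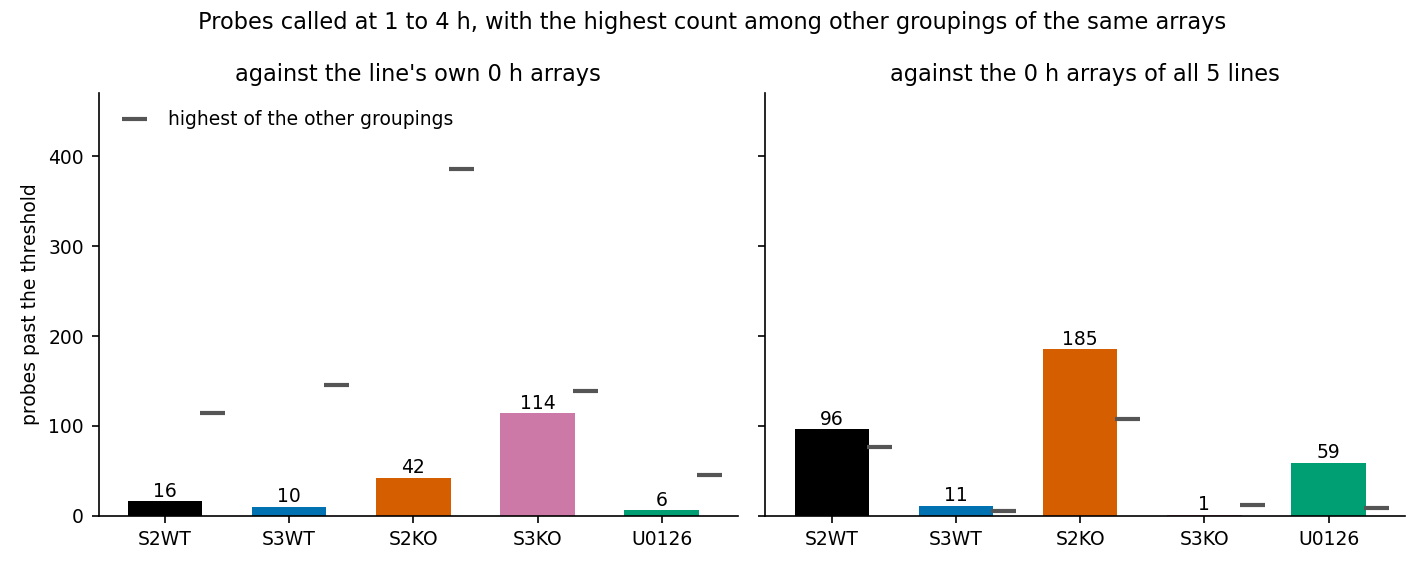
Number of probes called at 1 to 4 h in each line by limma, against the line's own 0 h arrays and against the 0 h arrays of all 5 lines pooled, with a dash at the highest count from other groupings of the same arrays. The pooled counts of 96, 11, 185 and 59 in S2WT, S3WT, S2KO and U0126 lie above their dashes, and the own counts of 16, 10, 42, 114 and 6 in S2WT, S3WT, S2KO, S3KO and U0126 below theirs. The other groupings for the pooled counts mix arrays of different lines, so lying above these dashes does not exclude chance.

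The 17 gene lists were tested in 9 contrasts, the 5 responses and 4 differences at 1 to 4 h, which makes 153 tests. Of these 13 passed against own 0 h arrays, and 2 with an estimated correlation, while 16 and 12 passed against the pooled ones. TGF-β pathway genes and early targets, 21 measured, were higher than other genes in all 3 of S2WT, S3WT and S2KO. In S2WT the median was 0.29 (adjusted p = 0.00561, and adjusted p = 0.204 with an estimated correlation). No member passed overall there and 4 higher and 1 lower passed adjusted over the list alone, among them Snai1 (1.22), Bhlhe40 (0.81), the repressor Tgif1 (0.69) and Tgfbr3 (-0.80). In S3WT the median was 0.18 (adjusted p = 0.000858, and adjusted p = 0.0749 with an estimated correlation), with 1 member past overall and 4 adjusted over the list alone, which were Bhlhe40, Smurf2 (0.76), Klf10 (0.82) and Tgif1 (0.61). In S2KO the median was 0.17 (adjusted p = 0.00182, and adjusted p = 0.0444 with an estimated correlation), with 3 past overall and 5 adjusted over the list alone. Against the pooled 0 h arrays the list was called in S2WT (median 0.25, adjusted p = 0.0413 with an estimated correlation), S3WT (0.19, adjusted p = 0.0205 with an estimated correlation), S2KO (0.32, adjusted p = 0.0013 with an estimated correlation) and U0126 (0.17, adjusted p = 0.0132, and adjusted p = 0.31 with an estimated correlation). The members past overall were then 5 higher and 1 lower in S2WT, 2 in S3WT, 8 higher and 2 lower in S2KO and 2 in U0126, and adjusted over the list alone 9 and 1, 8, 13 and 2, and 5 and 1.

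Immediate early genes, 20 measured, were higher in S3WT (median 0.32, adjusted p = 0.00689, and adjusted p = 0.0763 with an estimated correlation), with 0 members past overall by limma and 2 adjusted over the list alone. They were lower in U0126 than in S2WT (-0.30, adjusted p = 0.0344, and adjusted p = 0.272 with an estimated correlation). Against the pooled 0 h arrays they were higher in S3WT (0.23, adjusted p = 0.0325 with an estimated correlation) and S2KO (0.45, adjusted p = 0.00432 with an estimated correlation), where 6 rose and 1 fell overall and 9 and 2 adjusted over the list alone. The 6 genes of the direction list were higher in S2KO (0.34, adjusted p = 0.0223 with an estimated correlation), with 1 past overall and 2 adjusted over the list alone, and on pooled arrays in S2KO (0.24) and S3WT (0.08). The direction of the ratio was itself read from this list in S2WT and S3WT, so its rise in S3WT is no separate result. On the treated arrays of S3KO compared directly with S3WT, 3 of these lists were lower: immediate early genes (-0.25, adjusted p = 0.0078 with an estimated correlation), direction genes (-0.24, adjusted p = 0.0078 with an estimated correlation) and TGF-β genes (-0.06, adjusted p = 0.0212, and adjusted p = 0.118 with an estimated correlation). No member of them passed overall by limma, and 2, 2 and 5 lower ones passed adjusted over the list alone, beside 1 higher TGF-β gene. By the difference of responses against own 0 h arrays, none of the 3 lists passed for S3KO minus S3WT. The direct comparison keeps any difference in background between the lines, whose 0 h means correlated with r = 0.14. It also includes S3KO 1 h replicate 2, which correlated with the 0 h mean of the other lines at r = -0.38.

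Of the other lists, mitochondrial genes, 36 measured, were lower in S3WT (-0.16, adjusted p = 0.485 with an estimated correlation) and U0126 (-0.21, adjusted p = 0.588 with an estimated correlation). They were higher in S3KO than in S3WT (0.33, adjusted p = 0.494 with an estimated correlation) and lower in U0126 (-0.46, adjusted p = 0.272 with an estimated correlation) and S3WT (-0.34, adjusted p = 0.317 with an estimated correlation) than in S2WT. The 5 calls had adjusted p from 2.05e-05 to 0.00896 at the preset correlation, and none held with the estimated one. Ribosomal protein genes, 19 measured, were lower than in S2WT in U0126 (-0.33, adjusted p = 0.272 with an estimated correlation) and S3WT (-0.21, adjusted p = 0.336 with an estimated correlation), after adjusted p of 0.0334 and 0.0262 at the preset one. Against the pooled 0 h arrays actin and contractile genes, 16 measured, were higher in S2KO (0.21, adjusted p = 7.05e-05, and adjusted p = 0.084 with an estimated correlation), with 3 past overall and 4 adjusted over the list alone. Cell cycle genes, 25 measured, were lower there (-0.17, adjusted p = 0.0334 with an estimated correlation), with Cdc6 lower and Cdkn1a, an inhibitor of cell division, higher by 0.41 ± 0.10, a call kept in 9 of 22 fits that left out 1 array and lost without the S3KO 0 h arrays in the pool (adjusted p = 0.248). Mitochondrial genes were at 0.10 in S2KO (adjusted p = 0.381 with an estimated correlation) and 7 cholesterol genes at -0.17 in S3WT (adjusted p = 0.0446 with an estimated correlation). Markers of other cell types did not pass against own 0 h arrays, with a smallest adjusted p of 0.104 for endothelial and muscle, 0.335 for epithelial and 0.335 for macrophage markers. Against the pooled arrays the 8 endothelial and muscle markers were lower in S2KO (-0.19, adjusted p = 0.0334 with an estimated correlation), with 0 past overall by limma and 2 adjusted over the list alone, Flt1 (-1.75) and Emcn (-1.88). The smallest adjusted p there was 0.0793 for epithelial and 0.0642 for macrophage markers. The lists that passed in no contrast under either background were extracellular matrix (smallest adjusted p with own 0 h arrays 0.73, 24 genes), fibroblast markers (0.431), glycolysis (0.357), interferon response (0.495), proteasome (0.0801) and heat shock and endoplasmic reticulum stress (0.104). Of the genes always included, Smad3 and Smad7 passed in no response, for example Smad7 at 0.41 against the pooled arrays in S2WT (adjusted p = 0.167). Skil passed in S2KO but was at 0.52 in S2WT (adjusted p = 0.0659).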

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

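The tests in this part were all chosen after the results were seen, except the regroupings of the arrays for the comparisons with own 0 h arrays, which were planned but whose predictions were written afterwards.

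A difference between lines was past the threshold for 14 probes at 1 to 4 h. S2KO exceeded S2WT at Gys2 (4.33, with a 0 h difference of -3.52 and a treated difference of 0.81). It also did at Slc39a10 (1.13, 0 h -0.50, treated 0.64) and at Aass (2.40, 0 h -2.44, treated -0.03). S3KO was below S3WT at Tut4 (-1.96, 0 h 1.49, treated -0.47), Tgfbr3 (-3.44, 0 h 2.96, treated -0.48) and Scgb1a1 (-5.03, 0 h 3.89, treated -1.14). It was also below at Rnf144a (-2.05, 0 h 2.63, treated 0.57), Ankrd27 (-3.41, 0 h 3.60, treated 0.18) and Rora (-1.65, 0 h 1.16, treated -0.48). The last of these were Cenpa (-1.79, 0 h 1.48, treated -0.32), Asap3 (-1.20, 0 h 0.75, treated -0.45) and Tmed5 (-2.87, 0 h 2.70, treated -0.17). U0126 exceeded S2WT at Rprd1b (2.89, 0 h -3.0, treated -0.11) and at Gtf2h3 (3.60, 0 h -3.06, treated 0.54).

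At 13 of these 14 probes the 0 h means of the lines lay farther apart than the treated means. Calls of this kind favour such probes, since a 0 h mean rests on 3 arrays and a treated mean on 8 or 9. In other groupings of the same arrays 934 of 941 calls did the same. Differences between the 0 h arrays of the lines therefore cannot be told apart from chance here. Slc39a10 is the exception, and it was also called when treated arrays were compared directly. Low signal cannot be told apart either, because the 14 probes lacked a value on a median of 2 arrays against 1 for tested probes, and a share of 0.397 of random sets had as high a median. A difference between the lines in their response to TGF-β stays open and is not tested by these values.

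S3KO had the most calls of the 5 lines against its own 0 h arrays, 114. Over all 2244 probes measured on every array, the S3KO 0 h mean correlated with the 0 h mean of the other lines at r = 0.1355, against 0.61 to 0.76 for the other lines. Its replicates 1 and 2 (-0.16 and -0.10) lay below each of the 12 other 0 h arrays, of which the lowest had 0.23, while replicate 3 had 0.58. At 98.2% of the called probes the S3KO 0 h mean lay farther from the 0 h mean of the other lines than the treated mean did, but other groupings gave 95.4%, so that share decides nothing. The treated S3KO means lay a median of 0.14 log2 from the 0 h means of the other lines, against a median response of 1.51. Choosing probes by a large gap from a 0 h mean of 3 arrays favours this pattern too. It was not compared with other groupings, so it does not argue against a TGF-β response, which stays open. Low signal cannot be told apart, since 50% of the 114 had more missing values than the median probe, a share of 0.446 of random sets had as many, and missing values are only a stand-in for signal. A candidate explanation is therefore that 2 of the S3KO 0 h arrays stand apart from the rest, and what sets them apart is not given in the sources used here.

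Probes called in S2WT against the pooled 0 h arrays had small ratios on treated S3KO arrays. If ratios were compressed on all S3KO probes, the slope of treated means on the 0 h means of other lines should be low too, and it was 0.531 of that in S2KO against 0.224 for the score of called probes. Set against S3WT the slope ratio was 0.984 and the score ratio 0.467, which argues against compression relative to that line, but slopes over S3KO arrays spread by 0.49 around 0.52, so compression cannot be told apart. Among the treated S3KO arrays 1 h replicate 2 correlated with the 0 h mean of the other lines at r = -0.38, and the others at 0.31 to 0.65. Arrays without TGF-β RNA in the treated channel cannot be told apart either: there was 1 call against the pooled arrays, and a label of the S3KO 0.3 h arrays names no TGF-β for both channels. Loss of Smad3, which the line's name gives, stays open as an untested biological explanation.

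The arrays were regrouped at random 100 times to see whether chance could give as many calls. Against own 0 h arrays chance could not be excluded in any line. S2WT had 16 calls and other groupings up to 114 (22 of 100 had as many), S3WT 10 and up to 146 (38 of 100), S2KO 42 and up to 386 (20 of 100), S3KO 114 and up to 139 (5 of 100) and U0126 6 and up to 45 (45 of 100). Groupings that called several times the real count, as in S2WT, S3WT, S2KO and U0126, point to a structure of the samples, which was not identified. Arrays with the same replicate number had a mean r across genes of 0.10 in S2WT, 0.07 in S3WT, 0.16 in S2KO, 0.16 in S3KO and 0.03 in U0126, against -0.05, -0.03, -0.08, -0.08 and -0.02 for other numbers. These r values correlate deviations from the group mean, which sum to 0 within a group. The values for other numbers therefore largely follow from those for the same number and are no separate reference. Whether replicate number accounts for the extra calls was not tested. Noise that is not normal also gives extra calls, as permuted residuals gave 24 false calls of 124 on simulated data and normal noise 1 of 91. For the differences between lines chance could not be excluded either. S2KO against S2WT gave 3 with others up to 19 (7 of 100), S3KO against S3WT 9 and up to 184 (23 of 100), U0126 against S2WT 2 and up to 4 (13 of 100), and S3WT against S2WT 0 by limma, with 419 at an unadjusted p under 0.05, and up to 6 (100 of 100). Against the pooled 0 h arrays the real grouping had the most calls in S2WT (96, others up to 76), S3WT (11, up to 5), S2KO (185, up to 108) and U0126 (59, up to 9). There 1 of 100 groupings, the real one, had as many. In S3KO 39 of 100 had as many (1, up to 12). These regroupings put arrays of different lines into the same group, while the real grouping keeps lines apart. Differences in background between lines then widen the spread within groups and can lower the calls of the other groupings. Ranking first there therefore does not exclude chance. In the direct comparison of S3WT with S2WT (17, up to 4) 1 of 100 groupings, the real one, had as many. For S2KO against S2WT (26, up to 87) 3 of 100 groupings had as many. A grouping that calls several times the real count points to a structure of the samples here too. These regroupings also mix arrays of the compared lines, so the same limit holds and the shares do not exclude chance. Nor do they separate a response from a difference in background between lines. At 0.3 h the 10 splits per line are too few for a share under 0.05. The real and highest other counts were 0 by limma, with 520 at an unadjusted p under 0.05, and 19 in S2WT (10 of 10 had as many), 13 and 27 in S3WT (6), 2 and 24 in S2KO (9), 70 and 184 in S3KO (3) and 3 and 119 in U0126 (6).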

How the results depend on the processing

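Of the alternatives, those with pooled 0 h arrays, with the ceiling kept, without the S2WT 4 h arrays and with 0 h scores subtracted were chosen after the data were seen. Own-background counts moved by over 1.5 times in most alternatives, so the number of calls is not firm in any line, and signal over background, which limits every ratio, was not used here. Values come below in the order S2WT, S3WT, S2KO, S3KO, U0126 where 5 are given, and the cause was not tested unless the alternative tests fewer probes or arrays. Beside counts of 0 by limma, 201 to 673 probes had an unadjusted p under 0.05. The replicate block gave no count for the pooled and direct comparisons, which cannot be estimated with it. Where S3KO at 1 h was left with 1 array, that array is assumed to vary like the other groups.

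Treated arrays against 0 gave 1960, 733 and 2214 calls in S2WT, S3WT and S2KO and 1214 in U0126, and 329, 202, 537, 41 and 551 at 0.3 h. The differences gave 26 for S2KO, 0 for S3KO, 0 for U0126 and 17 for S3WT against their comparison lines, and 28 list tests passed. Signs turned for Cnih4 (-0.0817), Ankrd27 (-0.38, and -0.19 at 0.3 h), Rfxank (-0.15), Smurf2 probe 2306 in S3WT (-0.11), Igfbp5 (-0.45), Crybb3 (-0.27), Tpp1 (0.071), Wdr34 (0.31), Cul3 (-0.13), Pgrmc2 (-0.13), Pdha1 (-0.21), Rprd1b (-0.46), Mxi1 (-0.17) and Rere at 0.3 h (0.18). They also turned for the differences of Aass (-0.0334), Ankrd27 (0.18), Rnf144a (0.57) and Rprd1b (-0.11), for mitochondrial genes in S3WT (0.19) and U0126 (0.17), and for the S3WT-called score of S2WT minus S2KO (-0.0839) and S2KO minus U0126 (0.14).

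Without centring the counts were 3 in S3WT, 12 in S2KO, 3 in U0126, 6 in S3KO at 0.3 h and 3 for S3KO minus S3WT, 3 score pairs passed, and the direction list in S2WT was at 0.215. Scaling gave 58, 25, 7 and 203 in S2WT, S3WT, S2KO and S3KO, then 6, 1 and 1 at 0.3 h in S2WT, S2KO and U0126, 178 for the S3KO response 0.3 h, 34 for S3KO minus S3WT, 1 for U0126 minus S2WT, 1 score pair and 0.357 for the direction list. With scaling the S2WT-called score turned for S3WT minus S3KO (-0.0417) and S2KO minus U0126 (-0.0438), and Smad3 in S2WT was at 0.00795.

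With complete probes alone, which are fewer, the counts were 9 in S2WT, 4 in S3WT and 50 in S3KO, 2, 0, 14 and 0 at 0.3 h in S3WT, S2KO, S3KO and U0126, and 0, 1 and 1 for S2KO, S3KO and U0126 minus their comparison lines. The block gave 23 in S3WT, 3 and 6 at 0.3 h in S2WT and S2KO, and 28 for S3KO minus S3WT. With the lines compared alone, which are fewer arrays, the counts were 2, 2, 0, 0 and 0, then 1, 0, 0 and 0 at 0.3 h in S3WT, S2KO, S3KO and U0126, and 0, 0 and 0 for S2KO, S3KO and U0126 minus their comparison lines. Array weights gave 39, 42, 86, 54 and 16, then 29, 22, 41, 24 and 24 at 0.3 h, 17 for S3KO minus S3WT, 4 for U0126 minus S2WT, 1 for S3WT minus S2WT, and 0.00016 for Smad3 in S2WT. With array weights the pooled 0 h arrays gave 164, 38, 176, 1 and 171, and the treated arrays compared directly 70 for S2KO, 6 for S3KO, 1 for U0126 and 273 for S3WT against their comparison lines. Averaging by symbol gave 17 in S2KO, 64 in S3KO, 3 in U0126 and 44 in S3KO at 0.3 h. It turned Smad3 in S2WT (0.0837) and S3KO (-0.0885), Smad7 in S3WT (-0.57), Smurf2 probe 5215, U0126 response 1-4 h, against the pooled 0 h arrays (-0.0414), and the direct differences of Fam126a (-0.0260) and Prkcd (0.13).

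The pooled 0 h arrays gave 96 in S2WT, 185 in S2KO, 1 in S3KO and 59 in U0126, and 5, 31, 5 and 38 at 0.3 h in these lines. They turned the S3WT-called score of S2WT minus S2KO (-0.24) and S2KO minus U0126 (0.40). Without S3KO in the pool the counts were 61, 2, 144, 0 and 25, and 4, 13, 3 and 19 at 0.3 h in S2WT, S2KO, S3KO and U0126. Pgrmc2 (-0.41), Dppa5a (-0.32), Esco1 (0.20), Smad7 probe 5186, U0126 response 1-4 h (-0.000167) and Rere at 0.3 h (0.0416) turned. Own 0 h arrays turned Tsc22d1 in U0126 (-0.0050) and Msantd3 (0.0232) among genes of the pooled and direct results. Keeping the ceiling gave 52 in S2WT, 200 for the S3KO response 1-4 h and 12 in U0126, 2, 141 and 5 at 0.3 h in these lines, 0 for S2KO minus S2WT and 36 for S3KO minus S3WT, and turned Aass at 0.3 h (3.56). Without the S2WT 4 h arrays there were 7 calls in S2WT and 0 for S2KO minus S2WT, with Smad3 at 0.11. Subtracting the 0 h scores left 1 score pair and turned the S2WT-called score of S3WT minus U0126 (0.0542) and the S3WT-called score of S2WT minus S2KO (-0.153) and S2WT minus U0126 (-0.202).

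Leaving out 1 array gave 11 to 75, 2 to 57, 16 to 92, 45 to 418 and 4 to 29 calls at 1 to 4 h, and 1 to 21, 4 to 22, 1 to 63, 17 to 299 and 0 to 28 at 0.3 h. The differences ranged from 0 to 12 for S2KO, 0 to 189 for S3KO, 0 to 7 for U0126 and 0 to 11 for S3WT. The sign turned for Smad3 probe 401, S2WT response 1-4 h (-0.0546 to 0.0321) and S3WT (-0.141 to 0.0322) and for Smad7 probe 5186 in U0126 (-0.55 to 1.67, the lowest without 0 h replicate 2). Over these fits named genes kept sign and side of the threshold in 3731 values, lost the call in 760, gained it in 75 and turned in 6.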

Other observations

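The genes in this part were picked after their values were seen. Noct, the circadian gene nocturnin, was called against the pooled 0 h arrays in S2WT (1.0 ± 0.20, adjusted p = 0.00364), S3WT (0.90 ± 0.20, adjusted p = 0.0429) and S2KO (1.03 ± 0.20, adjusted p = 0.00107), with 9 treated arrays in each line. The S3WT call was kept in 10 of 22 fits that left out 1 array. Zfp36l1, which promotes decay of early-response mRNAs, fell in S2KO by 0.60 and kept this call in 24 of 24 such fits. Sirt1, a protein deacetylase gene, fell in S2WT by 0.66 ± 0.15, with the same 24 of 24. Its value was 0.10 in S3WT, and S3WT exceeded S2WT directly by 0.76, a call kept in 10 of 18 such fits.

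Of the 96 probes called in S2WT against the pooled 0 h arrays, 1 was farthest at 0.3 h, 18 at 1 h, 25 at 2 h and 52 at 4 h, although another label of the S2WT 4 h arrays gives 2 h. Of the 59 in U0126 the numbers were 0, 10, 23 and 26. Of the 114 called in S3KO against its own 0 h arrays they were 20, 39, 29 and 26. The response was defined from 1, 2 and 4 h, so a low number at 0.3 h follows in part from the choice of probes.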
